A study of Mus musculus with 6 samples.

How the data were processed

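Total RNA from the lungs of leptin-deficient ob/ob mice (strain B6.V-Lepob/J, females, about 1 month old) was measured on Affymetrix Mouse 430A arrays, 3 arrays from leptin-treated and 3 from saline-treated animals. Per the labels' protocols, RNA was extracted with Trizol, amplified and labelled from a T7-oligo(dT) primer in a small-sample procedure with repeated rounds of cDNA synthesis, and hybridised with external spiked-in controls. Each label gives 1 animal and 1 tissue per sample. No source used here states dose, duration or route of the treatment, a scan date or detection calls.

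The deposited values are linear probe set intensity values, 1 column per array. The software and the summarisation method are not given in the sources used here. A trimmed mean that leaves out the lowest and highest 2% of probe sets lies between 500.10 and 500.14 on each array, so each array had been scaled to a common mean, and no further normalization between arrays was found in the values. Such scaling raises every value of an array whose labelled RNA gave little signal, spiked-in controls and background included. For arrays, the number of arrays limits the precision.

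The table holds 22690 probe sets. The 64 control probe sets were left out of all tests, leaving 22626. Genes were taken from the platform's annotation table: 20380 probe sets have 1 symbol, 691 have several and 1555 have none, and only the first kind was named. Symbols were looked up by Entrez Gene ID in a RefSeq gene table (assembly GRCm38.p6), which changed 0 of them and lacked 29. No genome build is named for the array values, so no coordinates are given.

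Values were turned into log2(intensity + 22.0), where 22.0 is the 10th percentile of all values, which understates changes of dim probe sets. Probe sets in the lowest 30% by mean were left out, and 15838 were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend of variance on level, two-sided, contrast leptin minus saline), with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene was represented by its tested probe set with the highest mean. Gene lists with at least 5 tested members were compared with all other genes by limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 34 lists tested. The rule stated by the series was applied as a second criterion: a change of at least 1.5-fold, p under 0.05, and at least 6 of the 9 pairwise comparisons with 1.5-fold in the same direction. Its test is not named there, and a 2-sample test with pooled variance on the same log2 values was used.

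The groups, the tests, the 37 gene lists, the naming rule and most alternatives were fixed before the data were examined. The naming rule takes Lep and Lepr, then genes past the adjusted threshold without overlap between groups (up to 15 per direction), then, up to 10 per direction, genes at an unadjusted p under 0.05 with a change of at least 1.5-fold and no overlap, and then members of each list (those past the threshold, otherwise the 2 with the smallest p). List members are printed for the lists past the threshold, and for other lists the medians stand alone, a limit chosen after the values were seen. Genes with clone-like names are counted and not named. The whole comparison was repeated without saline replicate 1, an array left out in turn by plan, and the separate account of it with its own naming and list tests was chosen after seeing the data. In that fit 3 leptin and 2 saline arrays remain, and the series' rule asks for 4 of 6 pairwise comparisons.

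The labels do not say that the replicate numbers pair animals. The deviations of same-numbered arrays from their group means correlated at 0.103 to 0.144 across probe sets, against -0.147 to 0.0491 for arrays of different number, and 6 of 6 arrays correlated best with their own number. The correlations of numbers 2 and 3 were 0.109 and 0.142 without saline replicate 1. The deviations of the 2 saline arrays left are then mirror images, so these values are not separate checks. With all 3 correlations over 0.1, the numbers may pair the samples, on the evidence of the values alone. The main fits do not use this pairing. Fits with the replicate number as a block are given beside results whose call they change. Without saline replicate 1, leptin replicate 1 has no partner and adds nothing to the blocked fit.

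Alternatives were quantile normalization, a common median, pseudocounts of 1 and of the 25th percentile (79.9), no filter, a filter at 50%, the block, a variance prior without trend, array weights, leaving out each array, an adjusted threshold of 0.10, camera with an estimated correlation, fry, and the mean of a gene's probe sets. With an estimated correlation, camera also takes its degrees of freedom from the arrays and not from the genes. A call lost there is therefore not a matter of correlation alone.

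The fits were tested on simulated data with the real levels, spreads smoothed on level and independent noise for each probe set. In these, 100 probe sets changed 2-fold and 100 changed 4-fold, all drawn from probe sets above the median level. Recovery of dimmer probe sets was not simulated. With 6 arrays of like spread, 99% and 100% were recovered among 15838 tested. With the real values of saline replicate 1 in place of a simulated array, 0% and 0% were recovered. With 5 arrays, 96% and 98% were recovered. Simulated probe sets of like level shared the same spread, whereas real ones differ. These shares may therefore overstate how many real changes of that size pass the threshold. Of 30 simulated lists of 15 genes on 5 arrays, with 9351 genes in the test, camera called 5 of the 5 shifted by 0.3 on the log2 scale and 0 of the others. These simulated genes were uncorrelated, while the estimated correlation of the real lists reached 0.445 in T cell markers on 5 arrays. The simulation therefore does not show how often camera calls real lists falsely.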

Results

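Lung gene expression was compared between ob/ob mice given leptin and ob/ob mice given saline. These mice carry a mutation of the leptin gene and lack functional leptin, the adipocyte hormone that limits food intake, so the comparison asks which lung transcripts differ when the missing hormone is supplied. Each group had 3 arrays, and the p-values of single probe sets measure the spread between these 6 samples. The camera p-values of gene lists at the preset correlation compare a list's genes with the other genes. Genes, not animals, act as the replicates there, so these p-values do not measure the spread between animals. Xist, the transcript of the inactive X chromosome, read 7896 on saline replicate 1 and between 2697 and 3646 on the other 5 arrays for its brightest probe set, and 578 against 1055 to 1553 for the next. Of the Y-linked genes, Uty read 1108.1 on saline replicate 1 against 12.7 to 67.3 and 301.9 against 20.9 to 72.5 for its 2 probe sets, and Eif2s3y 84.9 against 1.2 to 3.4. The 3 Kdm5d probe sets went both ways, at 92.1 against 10.6 to 40.0, 94.8 against 7.6 to 19.0 and 50.3 against 76.0 to 137.6, and the 10th percentile of that array was itself raised, at 57.0.

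The array of saline replicate 1 stood apart from the other 5. Its log2 values correlated at 0.438 to 0.447 with theirs (Pearson's r across probe sets, which are not independent replicates), whereas the other 5 correlated with each other at 0.973 to 0.978. The first principal component held 92.0% of the variance over all 6 arrays and placed saline replicate 1 at 194.5 and the other arrays between -40.5 and -34.9. Over the other 5 arrays it held 29.8%, with leptin at -22.6, -2.44 and 21.2 and saline at -7.92 and 11.7. The groups thus overlapped along it, and also along the second component (26.6%). Spiked-in control probe sets on saline replicate 1 were a median 30.3-fold above their level on the other arrays, against ratios of 0.806 to 1.06 elsewhere. The 3' probe set of beta-actin read 1643 there and between 18527 and 19541 on the other arrays, and the 10th percentile of intensity was 57.0 against 16.3 to 19.2. Markers of the lung epithelium, 34 probe sets of the alveolar type II, alveolar type I and club cell lists, still ranked high on it, at a median percentile of 89.8 against 98.9 to 99.1 on the other arrays.

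**Figure D1:**
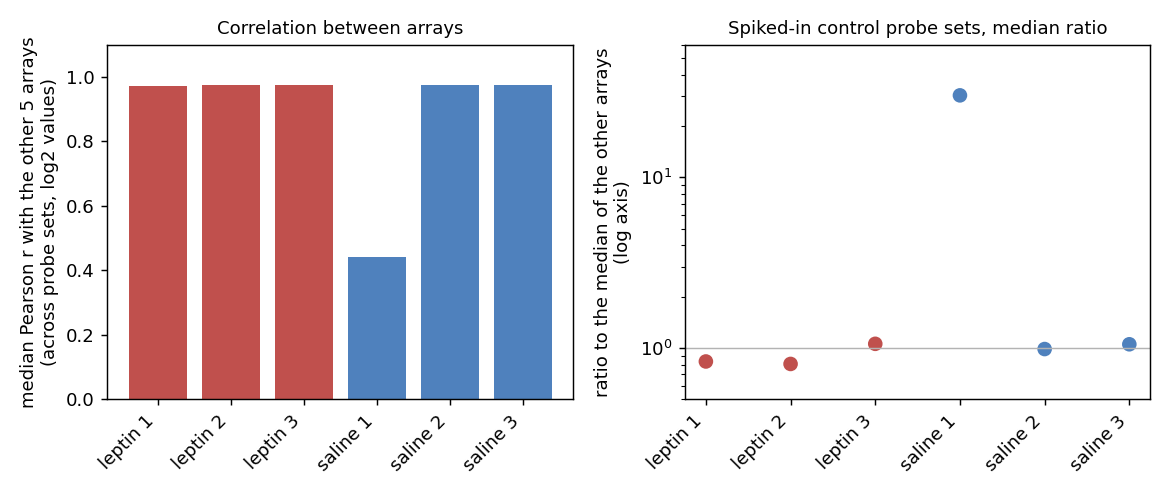
Left, median Pearson correlation of each array's log2 values with the other 5 arrays (axis from 0). Right, median ratio of the spiked-in control probe sets to their median on the other arrays (log axis). Red marks leptin and blue saline, 1 value per array, and saline replicate 1 has a correlation of 0.441 and a ratio of 30.3.

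With all 6 arrays, the comparison as designed, no probe set passed the adjusted threshold. In simulated data holding the real saline replicate 1, this fit recovered 0% of 2-fold and 0% of 4-fold changes. The lack of calls therefore does not show that expression was unchanged. The 10 named genes with higher values with leptin included Vcam1, an endothelial adhesion molecule, at 1.09 ± 0.32 (log2 change ± SE, n = 3 per group), Itgb2, the shared beta chain of leukocyte integrins, at 0.84 ± 0.27, Ifi27l2a, an interferon-inducible gene, at 0.70 ± 0.23, and Psmb9, an immunoproteasome subunit, at 1.24 ± 0.45. Bpifb1, a secreted airway protein, was at 1.40 ± 0.41, the heat shock genes Hsph1 and Dnajb1 at 1.52 ± 0.56 and 0.88 ± 0.34, the matrix genes Col6a3 and Lum at 0.74 ± 0.29 and 0.86 ± 0.33, and Ltf, a neutrophil granule protein, at 0.99 ± 0.39. The 10 lower genes were Rassf1, a tumour suppressor, at -1.34 ± 0.37, Rpl27a at -1.0 ± 0.34, Rsad2, an antiviral interferon target, at -1.13 ± 0.39, Shoc2 at -0.68 ± 0.25, Egr3, an immediate early transcription factor, at -2.46 ± 0.91, and Crygf, Capn8, Krtap21-1, Sypl2 and Csn3 at -1.13, -1.66, -1.92, -1.44 and -1.02. Several of these values leaned on saline replicate 1, where Egr3 read 2115.6 against 150.0 and 335.2 on the other saline arrays. Leaving it out gave -1.43 for Egr3, -0.74 for Crygf and Rsad2, -0.91 for Capn8 and -0.84 for Sypl2. Among the higher genes it gave 0.77 for Psmb9, 0.89 for Hsph1, 0.56 for Dnajb1 and 0.66 for Ltf. Krtap21-1, at 815.4 on saline replicate 1 and 121.9 and 162.4 on the other saline arrays, was then below the filter. None of these 20 genes passed the threshold, and the limma adjusted p was 0.715 for each. Shoc2 and Vcam1 each have another probe set with the opposite sign, at 0.67 and -0.14.

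At an unadjusted p under 0.05, limma gave 61 of 15838 probe sets, 32 higher and 29 lower, where chance alone gives about 792. Since this fit recovered no simulated change with saline replicate 1 present, the low count is no measure of a leptin effect. The series' stated rule was met by 32 probe sets, 17 higher and 15 lower, and 0 remained after Benjamini-Hochberg adjustment. Without saline replicate 1, 7 passed the adjusted threshold. The series' rule gave 78, 79 and 89 without saline replicate 1, 2 or 3 and 16 without leptin replicate 1. With limma's array weights, which gave saline replicate 1 a weight of 0.0257 against 1.64 to 2.98 for the others, 8 probe sets passed.

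Of the 34 gene lists tested on all 6 arrays, 10 passed the threshold, all higher with leptin: collagens, elastic fibre, glycoproteins and proteoglycans, the TGF-beta and BMP pathway, alveolar type II, alveolar type I, endothelial and smooth muscle markers, heat shock genes and oxidative phosphorylation. With an estimated correlation no list passed, and the smallest adjusted p was 0.654. With quantile normalization, a common median or a filter at 50% the endothelial list alone passed, with fry the collagen list alone, and 3 and 6 passed without leptin replicate 3 or saline replicate 3. Array weights kept the collagen, elastic fibre, smooth muscle and heat shock calls and ended the other 6: endothelial (adjusted p = 0.118), glycoproteins (0.0892), TGF-beta (0.564), type I (0.838), oxidative phosphorylation (0.990) and type II (0.615, with the direction turned to lower). With these weights the B cell, interferon-stimulated and MHC class II lists passed as higher (0.00127, 0.00309 and 0.00843) and the cholesterol and antioxidant lists as lower (0.0042 and 0.00517). The endothelial list had the smallest adjusted p (camera, 0.00176), with 16 of 18 markers higher and a median of 0.91, including Kdr at 0.55 ± 0.33 and Car4 at 0.91 ± 0.59. Napsa and Abca3, alveolar type II genes, were at 1.82 ± 1.43 and 1.18 ± 0.87, and Cldn18 and Sema3e of the type I list at 1.55 ± 1.16 and 0.92 ± 0.52. Mfap4 and Ltbp2 of the elastic fibre list were at 2.18 ± 1.30 and 0.81 ± 0.48, with Col15a1 at 0.96 ± 0.39 and Postn at 0.83 ± 0.57. Myh11 and Cnn1 of smooth muscle were at 1.41 ± 0.82 and 1.06 ± 0.51, Klf10 and Tgfbi of the TGF-beta list at 1.39 ± 0.82 and -0.70 ± 0.39, and Ndufs1 and Uqcrc1 of the respiratory chain at 1.05 ± 0.80 and 0.50 ± 0.38. Saline replicate 1 weighed on all of these genes but Col15a1: Tgfbi read 2043 on it against 1043 and 880 on saline replicates 2 and 3, and the others read lower there, with Napsa at 124.6 against 5691 and 5821. Without it the values were 0.35 for Kdr, 0.25 for Car4, 0.05 for Napsa, 0.13 for Abca3, 0.14 for Cldn18 and 0.35 for Sema3e. For Mfap4, Ltbp2 and Postn they were 0.59, 0.28 and 0.21, for Myh11 and Cnn1 0.42 and 0.50, for Klf10 and Tgfbi 0.40 and -0.34, and for Ndufs1 and Uqcrc1 0.11 and 0.14. Other probe sets went the opposite way for Abca3 (-0.34) and Tgfbi (1.27 and 1.08). No member of these lists passed the threshold over all probe sets or adjusted over the list alone. Without saline replicate 1 the median turned negative in alveolar type II markers (-0.11), alveolar type I markers (-0.02) and oxidative phosphorylation (-0.08), and the endothelial and TGF-beta lists no longer passed (adjusted p = 0.136 and 0.483). With the replicate block the collagen list no longer passed (adjusted p = 0.0728).

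Lep and its receptor were examined in every sample. The Lep probe set was dim, fell below the filter and was left out of the test. It read 59.1, 21.3 and 18.0 on the leptin arrays and 131.9 and 124.5 on saline replicates 2 and 3, with 70.3 on saline replicate 1. In the fit without a filter, Lep was at -1.30 ± 0.46 on 6 arrays (limma adjusted p = 0.737). Without saline replicate 1 it was at -1.53 ± 0.35 (0.651), so it passed in neither. The brightest Lepr probe set (Entrez Gene 16847) read 470 ± 101 (SD, n = 3) with leptin and 479 ± 70.1 (SD, n = 3) with saline, a log2 difference of -0.04 ± 0.27 (SE; limma adjusted p = 0.946). A second Lepr probe set read 349, 342 and 374 with leptin and 241 and 269 on saline replicates 2 and 3, with 76.2 on saline replicate 1. On all 6 arrays it had the opposite sign, at 0.94 (limma adjusted p = 0.715). Without saline replicate 1 the brightest probe set was at 0.07 ± 0.19 and the second at 0.45 ± 0.16, and neither passed the threshold (adjusted p = 1.00 for both).

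Without saline replicate 1, 7 probe sets of 6 genes passed the limma threshold, lower with leptin for Alas2, Slc25a37, Bpgm, Agpat5 and Rassf1 and higher for Bpifb1. Alas2 (Entrez Gene 11656), the first enzyme of haem synthesis in erythroid cells, read 3450 ± 537 (SD, n = 3) with leptin and 7887 ± 794 (SD, n = 2) with saline, a log2 change of -1.20 ± 0.15 (SE). Slc25a37 (67712), the mitochondrial iron importer of erythroid cells, was at -1.20 ± 0.14, and Bpgm (12183), which makes the red cell regulator of haemoglobin's oxygen affinity, at -1.16 ± 0.16. Agpat5 (52123), an acyltransferase of phospholipid synthesis, was at -1.78 ± 0.24, Rassf1 (56289) at -1.65 ± 0.21, and Bpifb1 (228801) was higher by 1.07 ± 0.15 on 1 probe set and by 0.98 ± 0.16 on its brighter one. The 7 probe sets, 1 higher and 6 lower, with 2 for Bpgm, were each at an adjusted p of 0.0496. With array weights on all 6 arrays, 5 of the 7 passed as well, and Alas2 and 1 Bpgm probe set did not (limma adjusted p = 0.140 and 0.0878). Saline replicate 1 had a weight of 0.0257 there, against 1.64 to 2.98 for the others. The weighted fit thus rests on nearly the same 5 arrays and is no separate check. Without weights, the brighter Bpifb1 probe set was at a limma adjusted p of 0.0956 on the 5 arrays. With saline replicate 1 included, Alas2, Slc25a37, Bpgm and Agpat5 were at 1.12, 0.27, -0.04 and -1.08, since they read low on that array, at 42.2, 52.2, 142.4 and 72.1.

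**Figure D2:**
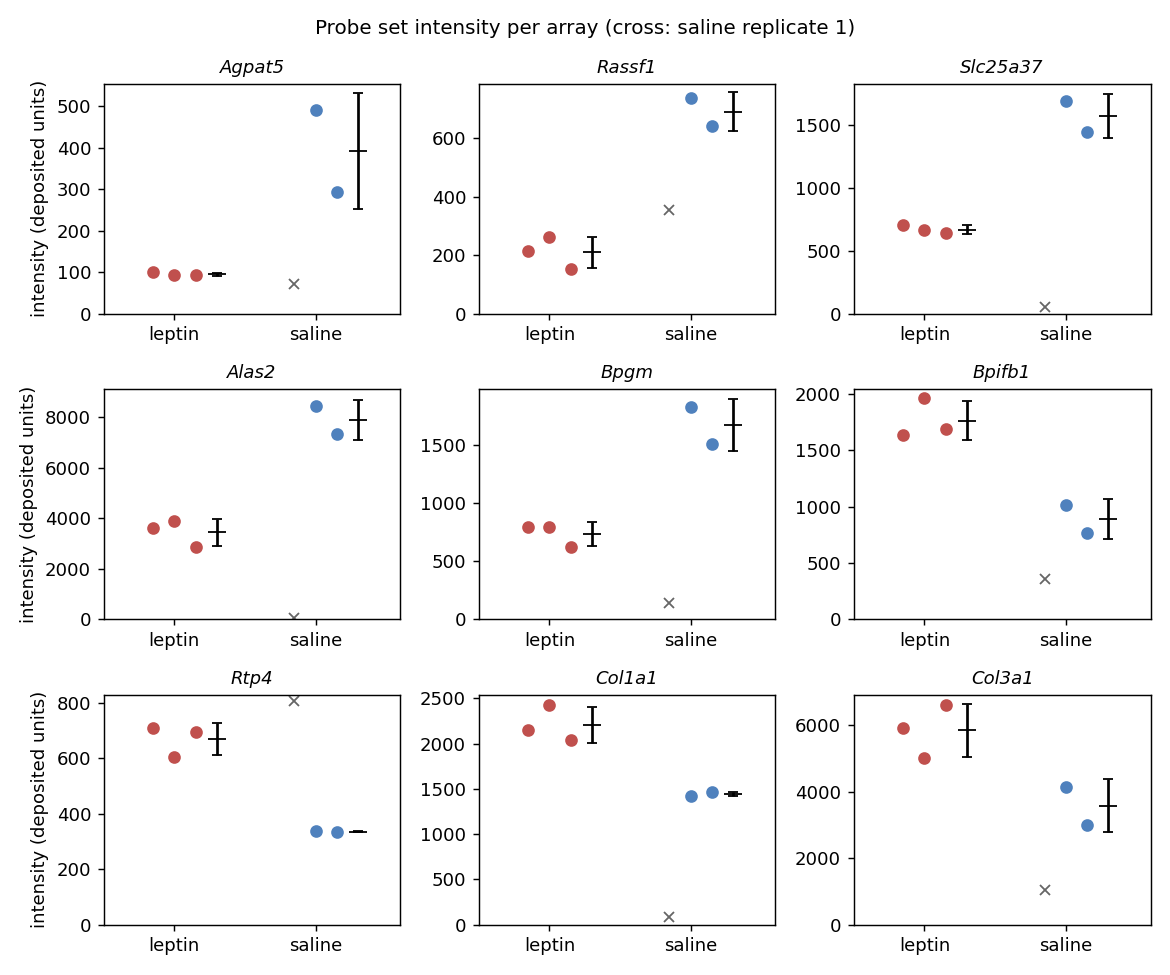
Deposited intensity of 9 genes' brightest tested probe sets on each array (linear axis from 0). Red points are leptin arrays, blue points saline replicates 2 and 3, crosses saline replicate 1, and black bars the mean and SD of the coloured points. Alas2 lay at 3450 ± 537 with leptin and at 7325 and 8449 on saline replicates 2 and 3, and read 42.2 on saline replicate 1.

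The next genes by the naming rule did not pass the threshold. Higher values with leptin were measured for Fen1, a DNA replication nuclease (1.27 ± 0.20), the interferon-inducible Rtp4 (0.95 ± 0.15) and Ifi27l2a (0.77 ± 0.15), Scn3b (0.77 ± 0.15), Hsph1 (0.89 ± 0.19), the fibrillar collagens Col1a1 (0.60 ± 0.13) and Col3a1 (0.71 ± 0.16), Psmb9 (0.77 ± 0.18) and Itgb2 (0.69 ± 0.17), with adjusted p from 0.0956 to 0.520. Another Fen1 probe set was at -0.17. With saline replicate 1 included, Fen1 turned to -0.83, since it read 15158 on that array against 177.8 and 164.4 on the other saline arrays. Rtp4, Col1a1 and Col3a1 were then at 0.55, 1.87 and 1.29. Lower values were measured for Ddit4, an inhibitor of mTOR signalling (-0.87 ± 0.16), Tent5c (-0.89 ± 0.17), Gnmt (-1.25 ± 0.24), Capn8 (-0.91 ± 0.18) and Fech, the last enzyme of haem synthesis (-0.79 ± 0.17), with adjusted p from 0.166 to 0.298. With saline replicate 1 included, Ddit4, Tent5c, Gnmt, Capn8 and Fech were at -0.19, -0.01, -0.49, -1.66 and -0.24. Of the erythroid list 3 genes were tested, and Slc4a1, the red cell anion exchanger, and Hbb-b2 were at -0.70 ± 0.25 and -0.79 ± 0.36. The groups overlapped for Hbb-b2, which ranged from -0.03 without saline replicate 2 to -1.54 without saline replicate 3, and Slc4a1 was at -0.44 without saline replicate 2. Another Hbb-b2 probe set was at 0.12.

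The 728 probe sets at an unadjusted p under 0.05 (414 higher, 314 lower) were fewer than the 792 that chance gives, and with the replicate block there were 1142 (562 higher, 580 lower). The 7 calls were lost with quantile normalization, a common median, a pseudocount of 1, no filter, the replicate block and a variance prior without trend, and 0 to 3 passed when another array was also left out, with 0 without leptin replicate 1 or saline replicate 3.

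Of the 34 lists tested without saline replicate 1, 15 passed the camera threshold, 10 higher and 5 lower with leptin. No list passed in camera with an estimated correlation (smallest adjusted p = 0.212) or with fry (smallest adjusted p = 0.0664). Over all probe sets 0 members of these 15 lists passed the threshold, and adjusted over the list alone 0 passed in each list for which no such count follows. The collagen list was higher in 15 of 17 genes, with a median of 0.29 (camera adjusted p = 3.07e-09, and 0.212 as the adjusted p with an estimated correlation). The estimate for this list was 0.00152, below the preset 0.01, so a stronger correlation does not account for the larger p. It lay below the preset value also in MHC class II, cholesterol and antioxidant genes (-0.123, -0.0474 and -0.00525). In B cell, club cell and elastic fibre genes it was 0.352, 0.234 and 0.197. For those 3 lists the preset value understates the estimated correlation. Of the collagen genes, 7 were higher at an unadjusted p under 0.05, 0 passed the threshold over all probe sets and 5 passed adjusted over the list alone. In the elastic fibre list 14 of 15 were higher (median 0.17, adjusted p = 0.00113, and 0.349 with an estimated correlation). Mfap4 was at 0.59 ± 0.15 and Fbln5 at 0.28 ± 0.13, and 1 passed adjusted over the list alone. Of glycoproteins and proteoglycans 19 of 26 were higher (median 0.10, adjusted p = 0.0287, and 0.349 with an estimated correlation). Lum was at 0.68 ± 0.23 and Tnc at 0.49 ± 0.23. Smooth muscle markers were higher in 9 of 11 (median 0.21, adjusted p = 0.0114, and 0.349 with an estimated correlation). Cnn1 was at 0.50 ± 0.18 and Myh11 at 0.42 ± 0.15. Leaving out saline replicate 3 as well ended the calls of the elastic fibre, glycoprotein and smooth muscle lists (adjusted p = 0.0543, 0.412 and 0.0726), and leaving out leptin replicate 3 ended the last 2 of these (0.149 and 0.120). Mfap4 was at 0.35 without saline replicate 3 and Lum at 0.45 without leptin replicate 3. The glycoprotein call was also lost without a filter (0.0604), with a filter at 50% (0.0502) and with no trend (0.0692).

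The MHC class II, B cell, interferon-stimulated and neutrophil lists were higher, and the T cell and macrophage lists did not pass the threshold (adjusted p = 0.0704 and 0.126). All 7 MHC class II genes, which present antigen to helper T cells, were higher (median 0.24, camera adjusted p = 0.00103, and 0.283 with an estimated correlation). H2-Eb1 was at 0.32 ± 0.12 and H2-Aa at 0.28 ± 0.12 (0.16 without saline replicate 2). B cell markers were higher in 9 of 10 (median 0.45, adjusted p = 0.000519, and 0.349 with an estimated correlation, which was 0.352 in this list). Cd37 and Fcer2a were both at 0.60, SE 0.21 and 0.23. Interferon-stimulated genes were higher in 14 of 16 (median 0.24, adjusted p = 0.00123, and 0.298 with an estimated correlation). Adjusted over the list alone 3 passed, Psmb9 and Gbp2 higher at 0.77 ± 0.18 and 0.60 ± 0.15 and Rsad2 lower at -0.74 ± 0.16. Neutrophil markers were higher in 8 of 10 (median 0.21, adjusted p = 0.0359, and 0.349 with an estimated correlation). Ltf was at 0.66 ± 0.21 and Ngp at 1.13 ± 0.47. The groups overlapped for Ngp, which ranged from 0.24 without saline replicate 3 to 2.02 without saline replicate 2, and Ltf was at 0.40 without saline replicate 2. The neutrophil call was lost when saline replicate 3, leptin replicate 2 or leptin replicate 3 was also left out (adjusted p = 0.899, 0.252 and 0.107), with quantile normalization (0.0670), a pseudocount of 1 (0.0520), no filter (0.0999) and no trend (0.107).

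The cell cycle and heat shock lists were higher. Among cell cycle genes 13 of 18 were higher (median 0.19, camera adjusted p = 0.0117, and 0.349 with an estimated correlation). Top2a, which untangles replicated DNA, was at 0.73 ± 0.20 and Birc5 at 0.59 ± 0.26. Among heat shock and unfolded protein genes 10 of 17 were higher (median 0.04, adjusted p = 0.00123, and 0.283 with an estimated correlation). Of its members 6 were at an unadjusted p under 0.05 and 2 passed adjusted over the list alone, with Hsph1 at 0.89 ± 0.19 and Dnajb1 at 0.56 ± 0.15. The cell cycle call was lost without saline replicate 3 (0.363) and turned in direction when the lowest 50% of probe sets were left out (median -0.07, adjusted p = 0.600).

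Lower lists were cholesterol synthesis, antioxidant and NRF2 targets, glucocorticoid-responsive genes, and alveolar type II and club cell markers. Cholesterol synthesis genes were lower in 12 of 14 (median -0.21, camera adjusted p = 0.00238, and 0.283 with an estimated correlation). Fdps was at -0.47 ± 0.16 and Fdft1 at -0.39 ± 0.14, although another Fdft1 probe set was at 0.27. Antioxidant and NRF2 target genes were lower in 14 of 16 (median -0.21, adjusted p = 0.000519, and 0.283 with an estimated correlation). Gclc, which limits glutathione synthesis, was at -0.60 ± 0.14 and Nqo1 at -0.73 ± 0.24, and 1 passed adjusted over the list alone. Glucocorticoid-responsive genes were lower in 11 of 14 (median -0.13, adjusted p = 0.00369, and 0.331 with an estimated correlation). Dusp1 was at -0.60 ± 0.13 and Per1 at -0.38 ± 0.15 (-0.18 without saline replicate 2 and -0.58 without saline replicate 3), and 1 passed adjusted over the list alone. Alveolar type II markers were lower in 9 of 12 (median -0.11, adjusted p = 0.0266, and 0.349 with an estimated correlation). Cebpa was at -0.30 ± 0.13 (-0.17 without saline replicate 3) and Sftpb, a surfactant protein, at -0.22 ± 0.10. Club cell markers were lower in 11 of 12 (median -0.09, adjusted p = 0.0491, and 0.494 with an estimated correlation). Cyp2b10 was at -0.24 ± 0.11 and Bpifa1 at 0.23 ± 0.11. The replicate block ended the calls of the glucocorticoid, type II and club cell lists (adjusted p = 0.0902, 0.204 and 0.506), as did leaving out leptin replicate 1 (0.109, 0.140 and 0.456) or saline replicate 3 (0.512, 0.506 and 0.813). The type II call was also lost without leptin replicate 3 (0.0654), and the type II and club cell calls with quantile normalization (0.278 and 0.426), a common median (0.0628 and 0.103), no filter (0.198 and 0.125) and no trend (0.153 and 0.189). The club cell call was also lost with a pseudocount of 1 (0.0520), a filter at 50% (0.0502) and array weights (0.0698). With saline replicate 1 included, the median had the opposite sign in the antioxidant (0.61), glucocorticoid (0.33), cholesterol (0.04), type II (0.68) and club cell (0.43) lists, and likewise in B cell (-0.12) and cell cycle (-0.36) genes, although the camera test of the cholesterol and B cell lists kept its direction, and of these 7 lists the type II list alone passed in the unweighted fit. With array weights on all 6 arrays the type II list did not pass (0.615), and the B cell, cholesterol and antioxidant lists passed in their direction without saline replicate 1 (0.00127, 0.0042 and 0.00517).

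**Figure D3:**
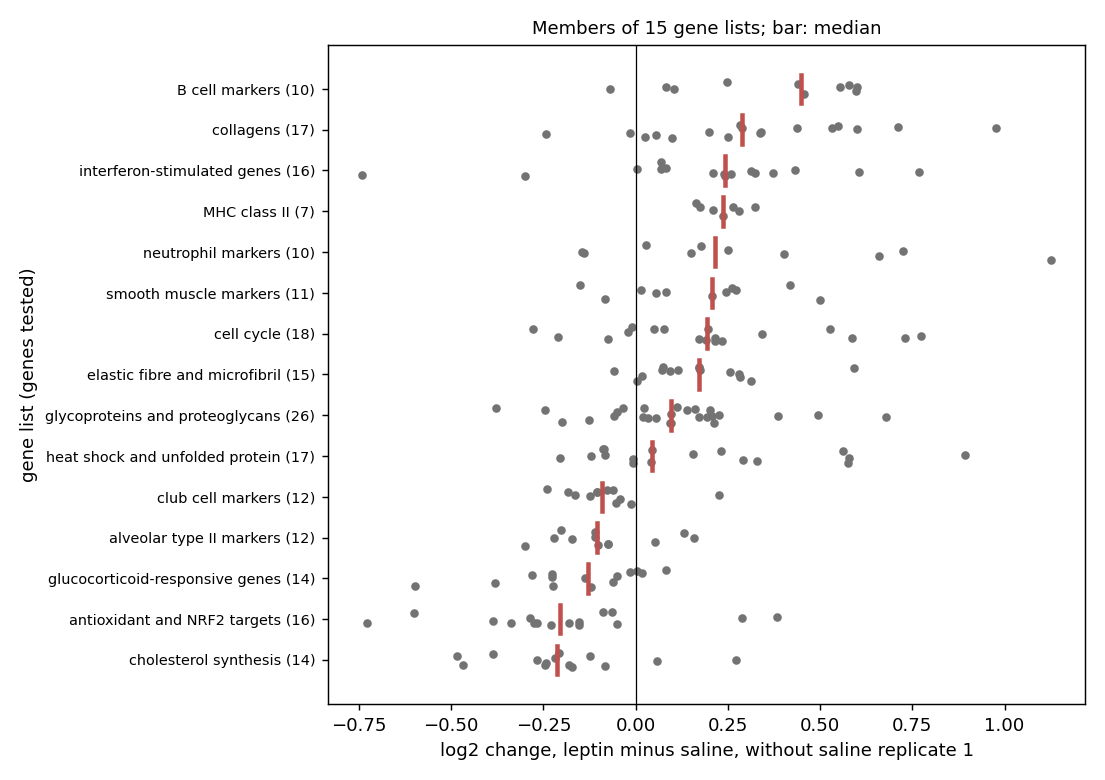
Log2 change (leptin minus saline, without saline replicate 1) of each tested member of the 15 gene lists past the camera threshold. Grey points are genes, red bars the medians, from 0.45 in B cell markers to -0.21 in cholesterol synthesis.

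The other 19 lists did not pass the threshold without saline replicate 1. Of the growth and matrix lists, the median was 0.04 for matrix proteases and inhibitors (adjusted p = 0.105), 0.03 for alveolar growth signalling (0.502), 0.06 for the TGF-beta and BMP pathway (0.483), 0.13 for the IGF axis (0.232) and -0.05 for retinoid signalling (0.815), whose mean was above 0 at 0.01. The leptin receptor and JAK-STAT list, the direct signalling path of the hormone, was at 0.06 with 10 of 18 genes higher (0.465). Among cell type markers the median was -0.02 for alveolar type I (0.535), 0.15 for ciliated cells (0.316), 0.05 for endothelium (0.136), 0.12 for macrophages (0.126), 0.16 for T cells (0.0704), 0.03 for adipocytes (0.465) and 0.03 for cardiac and skeletal muscle (0.483), and with the replicate block the muscle list passed (0.0119). Among metabolic and other lists it was -0.06 for fatty acid synthesis (0.138), -0.03 for fatty acid oxidation and PPAR targets (0.663), whose mean and test were positive, -0.07 for lipid uptake and storage (0.138), -0.08 for oxidative phosphorylation (0.391), 0.06 for immediate early genes (0.402) and -0.06 for the circadian clock (0.577). Thymocyte and erythroid lists had 2 and 3 tested genes and were not tested as lists.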

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

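The tests of saline replicate 1, of collagen level, of blood content and of the splits of 6 arrays by probe sets were chosen after their results or related values had been seen; the mesenchymal test and the other splits were set before, and the smooth muscle list was added to that test afterwards. Saline replicate 1 lay far from the other 5 arrays in all 6 technical measures compared over the 6 arrays: its median correlation with the others was 0.441, its spike ratio 30.3, its 10th percentile 57.0, its maximum 405950, its beta-actin 3' to 5' ratio 5.83 and its Gapdh 3' to 5' ratio 0.395. Chance marks about 1 in 20 such measures, and these 6 come from the same array and are not independent. Both 3' to 5' ratios rest on low readings there. Beta-actin 5' read 281.8 and Gapdh 3' and 5' 151.7 and 383.6, where the array's median was 323.75. The ratios are therefore no measure of RNA integrity on that array.

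Lung epithelial markers had a median percentile of 89.8 on that array (95% bootstrap interval 66.0 to 96.4). Their probe sets were the brightest of each gene, and no other probe sets of like level were compared. The rank therefore does not decide whether RNA of another tissue was the source of that array's profile. A low yield of labelled target is a candidate explanation, since spiked-in controls, added in a fixed amount, stood 30.3-fold above the other arrays. These controls are not RNA of the animal, so a difference in its lung expression alone would not raise them. The 3' probe set of beta-actin read 1643 there against 18527 to 19541 on the other arrays. These values argue against a difference in that animal's lung expression alone as the source of the array's whole profile. Whether the RNA of that sample or a later step was the source was not tested. For single genes on that array no biological explanation was tested.

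The collagen list was higher with leptin in the 5 remaining arrays, at a median of 0.29 (95% bootstrap interval over genes 0.10 to 0.53). Its call was lost in camera with an estimated correlation (adjusted p = 0.212) and with fry (adjusted p = 0.0664). The level or scaling of abundant probe sets is argued against: the median lay at percentile 100 of 10000 random lists matched on level, whose highest median was 0.17. A larger share of mesenchymal cells stays open: 9 markers outside the matrix lists, 5 higher and 4 lower, had a median of 0.12 (interval -0.12 to 0.19), below the collagens by 0.17 (0.05 to 0.49) where their own SD was 0.17. The bound set beforehand was met but had left out smooth muscle, a mesenchymal cell type whose list was higher (median 0.21, camera adjusted p = 0.0114, and 0.349 with an estimated correlation). A response of collagen genes to leptin stays open too, as a hypothesis, and with 2 saline arrays so does chance. The splits of the 5 arrays counted passing lists of every kind, and the collagen list by itself was not compared between splits. Of the 10 splits 1, the real one, gave as many gene lists, with 15 against at most 10 in the others. A share under 0.1 is out of reach with 10 splits.

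The 3 erythroid genes tested had lower values with leptin in the 5 arrays, with a median of -0.79 given by Hbb-b2, whose groups overlapped and which ranged from -1.54 to -0.03 with another array left out. Of the 3, Alas2 alone passed the threshold. Less blood in the samples may be the source and cannot be told apart, because markers of neutrophils, B cells and T cells had a median of 0.24 (interval 0.15 to 0.45) with 23 of 28 higher, while resident lung cells carry the same markers. Globin probe sets with several symbols ranged from -0.69 to -0.12, and the brightest of them were among the highest values of the arrays. Of the 10 splits of the 5 arrays, 1, the real one, gave as large a shift, 0.786 against at most 0.784 in the others, and 10 splits cannot give a share under 0.1. A lower share of reticulocytes or a response to leptin stays open and untested.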

How the results depend on the processing

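The results without saline replicate 1 as a separate account, with all their alternatives, were chosen after seeing the data; the other alternatives were planned. With all 6 arrays, 0 probe sets passed under the other planned settings, with 44 to 121 at an unadjusted p under 0.05 outside the array weights and the left-out arrays, against 8 with array weights, 32 by the series' stated rule and 0 to 7 with an array left out. The series' rule gave 114 without a filter and 16 to 89 with an array left out. Of the gene lists, 10 became 1 with quantile normalization, a common median, a filter at 50% or fry, 0 with an estimated correlation, and 3 to 15 with an array left out. The common median moved the median change of all probe sets from 0.02 to 0.17. The replicate block gave 0 probe sets and 9 lists. The cause of these shifts was not tested.

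Without saline replicate 1, 7 probe sets became 13 at an adjusted p under 0.10, 78 by the series' rule, 0 with quantile normalization, a common median, a pseudocount of 1, no filter, a prior without trend or the replicate block, and 0 to 3 with another array left out. The series' rule gave 242 without a filter and 72 to 145 with another array left out. The 15 lists became 13 with the block, 0 with an estimated correlation or fry, and 9 to 17 with another array left out; 7 of them, collagens, B cell markers, cholesterol synthesis, interferon-stimulated genes, MHC class II, heat shock and antioxidant genes, passed in the same direction under all settings but these last tests. Where 1 saline array remained, it was taken to vary like the leptin arrays. The cause of these shifts was not tested. Detection calls were not used here, and readings near the 10th percentile of 22.0 have no measured floor.

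Within the fit of 6 or of 5 arrays signs turned as follows. On 6 arrays the signs of Alas2 and of the type I, type II and oxidative phosphorylation medians rested on saline replicate 1. They turned where it was left out, and for Alas2 and the type II list also with array weights. For the other turns the cause was not tested. Lepr on 6 arrays (-0.04 as designed) was at 0.061 with quantile normalization, 0.109 with a common median, 0.057 with array weights and -0.195 to 0.0853 with an array left out, and on 5 arrays at -0.087 with the block and -0.0869 to 0.193 with another array left out. Of the erythroid genes on 6 arrays, Alas2 was at -1.17 with array weights and -1.2 to 2.33 with an array left out, Slc4a1 at 0.018 with quantile normalization and -0.700 to 0.244, and Hbb-b2 at -0.786 to 0.0464. The lowest value of Alas2 came without saline replicate 1 and the highest of Slc4a1 and Hbb-b2 without saline replicate 2. The type II list on 6 arrays had a median of -0.091 with array weights and -0.106 to 1.11 with an array left out, the type I list -0.0159 to 0.941 and oxidative phosphorylation -0.0819 to 0.865, each lowest without saline replicate 1. On 5 arrays the cell cycle list had a median of -0.074 with a filter at 50%.

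Of the 10 splits of the 6 arrays, 5 gave as many probe sets at an unadjusted p under 0.05 (61, and at most 86 in the others) and 2 as many lists (10, at most 12); of the 4 splits that part all 3 pairs, the others gave at most 50 and 6. Of the 10 splits of the 5 arrays, 1 gave as many probe sets past the threshold (7, at most 5), while at an unadjusted p under 0.05 the real split gave 728 and another 1244; of the 4 that part both pairs, the others gave at most 3 and, for lists, 6. Neither design can give a share under 0.1.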
